A study of Arabidopsis thaliana with 30 samples.

How the data were processed

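The data are RNA-seq measurements of whole rosettes of Arabidopsis thaliana. Plants of the wild type Ler and of the photoreceptor mutants uvr8-2 and cry1cry2 spent 6 h outdoors under 1 of 5 sunlight filters. Per the labels, each library held RNA of 2 field blocks, with 5 rosettes pooled per block sample, and was made with a stranded mRNA kit. The 30 libraries fall into 15 groups (3 genotypes by 5 filters) of 2 libraries each, taken from the titles.

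The authors deposited estimated counts per gene in 1 table of 34212 loci. Per the submitters' processing notes, FastQC, Trimmomatic 0.33 and kallisto were used. The roles of these tools, the kallisto version, the transcriptome, the step from transcripts to genes and the strand setting are not given in the sources used here. The values are not whole numbers. Of the values above 0, 40.1% were multiples of 1 over 4000, within a tolerance of 0.0001. The estimated counts were rounded to whole numbers before testing. Totals ran from 12109222 to 22865826 per library, and 6365 loci were at 0 in all libraries. Of the loci, 97.7% were found in the reference gene table, which was used only for symbols. Which genes neighbour each other was taken from the order of the locus codes. No coordinates are given, because the sources used here name no genome build.

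Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter on low counts was filterByExpr by group, which left 19980 genes, and library sizes were scaled with TMM factors between 0.93 and 1.11. A robust quasi-likelihood model had 1 coefficient per group over all 30 libraries, with 15 residual degrees of freedom and a common biological coefficient of variation of 0.125. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, whatever its fold. The p-values measure the spread between pooled libraries of 1 outdoor day.

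There were 24 comparisons, fixed with their tests before the data were examined. 12 of them are steps between neighbouring filters in 1 genotype, 8 ask whether a step differs between a mutant and Ler (an interaction contrast), and 4 compare a mutant with Ler under UVA+B or blue0. The UV-B step is UVA+B minus UVA, the short UV-A step UVA minus UVA350, the long UV-A step UVA350 minus UV0, and the blue step UV0 minus blue0. These names follow the filter names, since the labels give no wavelengths for the filters.

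Gene lists, also fixed beforehand from textbook knowledge, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2. The p-values were adjusted over the 20 lists of each comparison. The lists cover UVR8-HY5 signalling, flavonoid and phenylpropanoid enzymes, flavonoid regulators, sinapate ester synthesis, photolyases and DNA damage response, photoreceptors and blue-light signalling, shade and PIF targets, auxin response, the circadian clock and photoperiod, and light harvesting with Rubisco small subunits. They further cover chlorophyll synthesis, jasmonate synthesis and response, salicylate and pathogen defence, heat shock, the reactive oxygen response, aliphatic glucosinolate synthesis, flowering and floral organ markers, root markers, guard cell and phloem markers, and reference genes. All 286 listed loci were in the table. Members called were counted over all genes tested and adjusted over the list alone, and camera was repeated with an estimated correlation.

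Genes named in the text follow a rule fixed beforehand. For each step in Ler it takes the 8 called genes with the largest change in each direction, and for other comparisons 5, with a mean of at least 5 CPM in the highest group. For steps and genotype comparisons, both libraries of 1 group had to lie above both of the other. It adds up to 4 members with the smallest adjusted p of each list called by camera, and a fixed set of UV and blue-light genes. The end of a ranking may be left out for length. Where a group held 0 counts, a fold is a lower bound from 3 counts over the group. With 1 to 3 counts, the ratio is given with an exact 95% interval, which covers counting error only. Estimated counts of near-identical copies (LHCB1, RBCS and SAUR19 to SAUR24 genes) are uncertain, because reads are shared between them.

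The code was tested on simulated counts with known changes, made in 200 genes of the Ler UVA+B group only. For the UV-B step in Ler, over 19750 simulated genes past the filter, edgeR recovered 25.4% of genes changed 1.5-fold, 66.2% of those changed 2-fold and 89.1% of those changed 4-fold, and called 9 unchanged genes. For the difference of that step between cry1cry2 and Ler, it recovered 6.0%, 30.8% and 82.8%, and called 4 unchanged genes. DESeq2, run on 19980 genes, recovered 29.9%, 59.7% and 86.4% for the UV-B step in Ler and called 14 unchanged genes. Of 200 simulated unchanged lists of 15 genes, camera gave p under 0.05 for 2.5%. The simulated genes varied independently of each other. The 2.5% is therefore no error rate for lists whose genes vary together.

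The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a replicate block, only the libraries of 1 genotype in the fit, and leaving out each library in turn. A lone library left in a group is then assumed to vary like the other groups. Leaving out together the 3 libraries with over 1% chloroplast counts was added after the data were seen.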

Results

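Transcript levels were measured by RNA-seq in rosettes of 3 week old Arabidopsis thaliana plants kept for 6 h under filtered sunlight. The long-pass filters are named UVA+B, UVA, UVA350, UV0 and blue0. The 3 genotypes were the wild type Ler, uvr8-2, which is mutated in the UV-B photoreceptor UVR8, and cry1cry2, which is mutated in the blue-light receptors cryptochrome 1 and cryptochrome 2. The series was made to ask what UVR8 and the cryptochromes contribute to gene expression in sunlight. Every group held 2 libraries. Library totals lay between 12109222 (Ler UV0 replicate 1) and 22865826 (uvr8-2 blue0 replicate 1) estimated counts. Chloroplast genes took 0.123% to 1.585% of the counts, and over 1% in uvr8-2 blue0 replicate 2 (1.585%), cry1cry2 UVA+B replicate 2 (1.165%) and cry1cry2 UVA replicate 2 (1.316%). In each group the replicates differed by more than sampling noise, with a chi-square per degree of freedom of 9.7 to 42.9. Log2 fold changes are given with their standard errors, and group levels as mean ± SD in CPM with n = 2. A gene was called at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts at an unadjusted p under 0.05 stand beside some counts of calls. Without any change, a share of about 0.05 of the 19980 genes tested would lie there. Such a count alone therefore shows no hidden response. Where a list called by camera is given with its median alone, 0 of its members were called over all genes or over the list alone.

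The mutated genes were still transcribed in the mutants. UVR8 (AT5G63860) stood at 143 ± 2 CPM in uvr8-2 and 114 ± 1.9 CPM in Ler under UVA+B, a log2 difference of 0.32 ± 0.09 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0166). Under the other filters UVR8 differed by 0.09 to 0.18 and was not called. CRY1 (AT4G08920) differed between cry1cry2 and Ler by -0.35 ± 0.11 (UV0) to -0.84 ± 0.12 (UVA+B), and was called under each filter except UV0. CRY2 (AT1G04400) differed by -0.31 ± 0.18 (UV0) to -0.81 ± 0.18 (UVA+B) and was called under UVA+B and blue0. Without each library in turn, the calls of UVR8 under UVA+B and of CRY2 under UVA+B were lost in 3 of 4 fits each and that of CRY2 under blue0 in 4 of 4, while CRY1 kept its calls under UVA+B and blue0. A mutant allele need not alter the transcript level, so for UVR8 these values do not check the labels.

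The UV-B step in Ler raised genes of flavonoid synthesis, DNA repair and UV signalling. The largest rise among named genes was in AT2G22590, a UDP-glycosyltransferase gene, from 3.55 ± 1.6 to 60.2 ± 22 CPM (log2 4.08 ± 0.42), followed by AT1G64340 (3.53 ± 0.28). CHS (AT5G13930), which encodes chalcone synthase, the entry enzyme of flavonoid synthesis, rose from 1700 ± 490 to 5190 ± 150 CPM (1.61 ± 0.29). The flavonol regulator MYB12 (AT2G47460) rose by 2.49 ± 0.36, and the photolyase genes UVR3 (AT3G15620) and PHR1 (AT1G12370), which repair UV damage to DNA, by 2.51 ± 0.35 and 1.15 ± 0.21. Among the genes that fell were the transcription factor gene BZIP34 (AT2G42380, -1.39 ± 0.22), CHAT (AT3G03480, -1.51 ± 0.32), an acetyltransferase gene of leaf volatile synthesis, and PRE1 (AT5G39860, -1.30 ± 0.30), a growth-promoting regulator.

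Of 24 flavonoid and phenylpropanoid enzyme genes, 18 rose and none fell in Ler at the UV-B step (21 adjusted over the list alone), with a median log2 change of 1.59. Examples are CHI (AT3G55120, 1.63 ± 0.21) and C4H (AT2G30490, 1.61 ± 0.21). The list had a camera adjusted p = 3.72e-25, with adjusted p = 0.063 with an estimated correlation. Flavonoid regulators rose in 7 of 12 cases (9 over the list alone), with a camera adjusted p = 2.51e-07 and adjusted p = 0.0474 with an estimated correlation. UVR8-HY5 signalling genes rose in 6 of 18 cases (8 over the list alone, camera adjusted p = 3.35e-07, adjusted p = 0.114 with an estimated correlation), among them RUP1 (1.87 ± 0.38) and RUP2 (1.13 ± 0.24), repressors of UVR8. HY5 at 0.80 ± 0.24 was not called. Sinapate ester genes rose in 3 of 5 cases (3 over the list alone, camera adjusted p = 0.00354, adjusted p = 0.0997 with an estimated correlation). Photolyase and DNA damage genes rose in 5 of 16 (6 over the list alone, camera adjusted p = 0.00356, adjusted p = 0.114 with an estimated correlation).

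Other lists lay lower as sets in Ler at the UV-B step with few or no members called. Shade and PIF targets had a median of -0.48 (0 of 17 called, 0 over the list alone, camera adjusted p = 0.0019, adjusted p = 0.263 with an estimated correlation). Auxin response genes had a median of -0.77 (0 of 14, 0 over the list alone, camera adjusted p = 0.0019, adjusted p = 0.326 with an estimated correlation). Light harvesting and Rubisco genes had a median of -0.29, with RBCS2B the single member called (-0.83 ± 0.20; over the list alone 4 lower and 1 higher; camera adjusted p = 0.000127, adjusted p = 0.263 with an estimated correlation). Jasmonate genes had a median of -0.32 (0 of 24, 0 over the list alone, camera adjusted p = 0.00148, adjusted p = 0.497 with an estimated correlation). Aliphatic glucosinolate genes had a median of -0.14 (0 of 13, 0 over the list alone, camera adjusted p = 0.00266, adjusted p = 0.263 with an estimated correlation). Flowering and floral organ markers (median 0.04, camera adjusted p = 0.455), root markers (0.19, 0.636), guard cell and phloem markers (-0.03, 0.632), the circadian clock (0.40, 0.455), chlorophyll synthesis (-0.10, 0.636) and salicylate defence (0.01, 0.955) were not called as lists. The same holds for reference genes (camera adjusted p = 0.745), heat shock (0.351), the reactive oxygen response (0.115) and photoreceptors (0.0702).

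In all, 607 genes were called at the UV-B step in Ler, 445 higher and 162 lower. The count was 119 without Ler UVA replicate 2 (109 higher, 10 lower), 166 without Ler UVA+B replicate 2 (156 higher, 10 lower) and 312 without Ler UVA replicate 1 (230 higher, 82 lower). Of 42 called genes covered by the naming rule, 13 stayed called without each of the 4 libraries in turn, among them AT2G22590, AT1G64340, F3'H, CHI, C4H, MYB12, UVR3 and BZIP34. The other 29, CHS, PHR1, CHAT and PRE1 among these, lost the call in at least 1 such fit.

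In uvr8-2 no single gene was called at the UV-B step, while camera called 7 lists, each of them lost with an estimated correlation. CHS stood at 767 ± 320 CPM under UVA and 1630 ± 300 CPM under UVA+B (log2 1.09 ± 0.28), FLS1 (AT5G08640), which encodes flavonol synthase, differed by 1.37 ± 0.35 and MYB12 by 2.12 ± 0.46. Adjusted over the list alone, 14 of the 24 flavonoid enzyme genes rose (median 0.88, camera adjusted p = 4.9e-19, adjusted p = 0.136 with an estimated correlation). Of 12 flavonoid regulators, 5 rose over the list alone (median 0.58, camera adjusted p = 9.92e-06, adjusted p = 0.118 with an estimated correlation). UVR8-HY5 genes had a median of 0.30 (0 of 18 called, 0 over the list alone, camera adjusted p = 0.000117, adjusted p = 0.302 with an estimated correlation). For sinapate ester genes the median was 0.40 (0 of 5 called, 3 higher over the list alone, camera adjusted p = 0.00964, adjusted p = 0.136 with an estimated correlation). The median of shade and PIF targets was -0.11 (0 of 17 called, 0 over the list alone, camera adjusted p = 0.00964, adjusted p = 0.422 with an estimated correlation). Jasmonate genes had a median of -0.21 (0 of 24 called, 0 over the list alone, camera adjusted p = 0.00964, adjusted p = 0.633 with an estimated correlation). For aliphatic glucosinolate genes the median was 0.09 (0 of 13 called, 0 over the list alone, camera adjusted p = 0.0204, adjusted p = 0.422 with an estimated correlation). The 445 genes that rose in Ler had a median of 0.75 in Ler, where their choice raises it. In uvr8-2 their median was 0.29, and 91.0% were above 0. The 1343 genes that rose in cry1cry2, chosen from libraries that enter neither value, had a median of 0.38 in Ler and 0.10 in uvr8-2. edgeR called 0 genes in uvr8-2, with 1204 at an unadjusted p under 0.05, and DESeq2 called 37. Without uvr8-2 UVA+B replicate 2, edgeR called 34.

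A direct test of the difference between uvr8-2 and Ler at the UV-B step called 1 gene, RAD52-2 (AT5G47870), a RAD52-type gene. RAD52-2 stood at 116 ± 15 CPM in Ler under UVA+B and 38.5 ± 0.071 CPM under UVA, against 38.4 ± 4.3 and 31.3 ± 2.5 CPM in uvr8-2, a difference of responses of -1.29 ± 0.16 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00163). For CHS the difference was -0.53 ± 0.39, for MYB12 -0.38 ± 0.59 and for RUP1 -0.98 ± 0.56, none of them called. The flavonoid enzyme list had a median difference of -0.66 (0 of 24 called, 2 lower over the list alone, camera adjusted p = 1.75e-06, adjusted p = 0.529 with an estimated correlation). The photolyase list had a median difference of -0.13 (0 of 16 called, 2 lower over the list alone, camera adjusted p = 0.0383, adjusted p = 0.529 with an estimated correlation). Camera also called aliphatic glucosinolate genes (0.28) and light harvesting and Rubisco genes (0.26), each with its median difference. Each had a camera adjusted p = 2.93e-05 to 0.000787, with adjusted p = 0.478 to 0.529 with an estimated correlation. At an unadjusted p under 0.05 there were 1433 genes, and DESeq2 called 27. The count of 1 became 9 without Ler UVA+B replicate 1, 2 without uvr8-2 UVA+B replicate 1, 18 without uvr8-2 UVA+B replicate 2 and 2 without uvr8-2 UVA replicate 2, and RAD52-2 stayed called in each fit.

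At the UV-B step in cry1cry2, CHS rose from 1400 ± 340 to 5950 ± 770 CPM (2.09 ± 0.29), and ELIP1 (AT3G22840), which encodes a light-stress protein of the thylakoid, from 666 ± 220 to 5510 ± 590 CPM (3.05 ± 0.42). Genes that fell included GASA6 (AT1G74670, -2.82 ± 0.37), a gibberellin-regulated gene, EXPA8 (AT2G40610, -2.43 ± 0.36), which encodes a cell wall expansin, and PIF4 (AT2G43010, -1.17 ± 0.14), a growth-promoting regulator. Flavonoid enzyme genes rose in 20 of 24 cases (20 higher and 1 lower over the list alone, median 1.95, camera adjusted p = 4.9e-21, adjusted p = 0.0756 with an estimated correlation). Light harvesting and Rubisco genes fell in 13 of 20 cases, while PSBS, a photoprotection gene, rose by 0.66 ± 0.11 (16 lower and 1 higher over the list alone, camera adjusted p = 6.91e-07, adjusted p = 0.126 with an estimated correlation). LHCB5 (-0.73 ± 0.14), LHCB4.1 (-0.64 ± 0.12) and LHCA1 (-0.71 ± 0.14), which encode antenna proteins, were among those that fell.

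Auxin response genes fell in 8 of 14 cases in cry1cry2 at the UV-B step (11 over the list alone, median -1.20, camera adjusted p = 8.78e-05, adjusted p = 0.227 with an estimated correlation), among them IAA29 (-2.03 ± 0.50), a repressor of auxin signalling. Shade and PIF targets fell in 5 of 17 cases (6 over the list alone, camera adjusted p = 4.76e-05, adjusted p = 0.119 with an estimated correlation). Aliphatic glucosinolate genes fell in 4 of 13 cases (6 over the list alone, camera adjusted p = 0.000183, adjusted p = 0.126 with an estimated correlation). Further lists called by camera were UVR8-HY5 genes (0.91, 8 higher of 18, 11 higher over the list alone), flavonoid regulators (1.11, 8 higher of 12, 10 higher and 1 lower over the list alone), sinapate ester genes (1.05, 3 higher and 1 lower of 5, 3 higher and 1 lower over the list alone), photolyase and DNA damage genes (0.12, 5 higher of 16, 6 higher over the list alone) and jasmonate genes (-0.37, 2 lower of 24, 2 lower over the list alone), each with its median. They had a camera adjusted p = 1.02e-06 to 0.049, with adjusted p = 0.0744 to 0.675 with an estimated correlation. In all 2799 genes were called, 1343 higher and 1456 lower. Of the higher ones 405 were also higher in Ler, against 29.9 for independent lists, and of the lower ones 146 were lower in Ler, against 11.8. The difference between cry1cry2 and Ler was called by edgeR for 0 genes (656 at an unadjusted p under 0.05, 1 by DESeq2, and 1 by edgeR without Ler UVA+B replicate 2). For CHS it was 0.48 ± 0.39, and for ELIP1 1.27 ± 0.56. For this difference camera called flavonoid enzyme genes (0.29), light harvesting and Rubisco genes (-0.40), shade and PIF targets (-0.32, 0 of 17, 1 lower over the list alone) and auxin response genes (-0.47), each with its median difference. These had a camera adjusted p = 0.0018 to 0.0429, with adjusted p = 0.631 with an estimated correlation. The count in cry1cry2 was 1138 without UVA+B replicate 1, 1561 without UVA replicate 1, 1412 without UVA+B replicate 2, 1346 without UVA replicate 2, and 616 without the 3 libraries of over 1% chloroplast counts. IAA29 lost its call without at least 1 of the libraries.

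**Figure D1:**
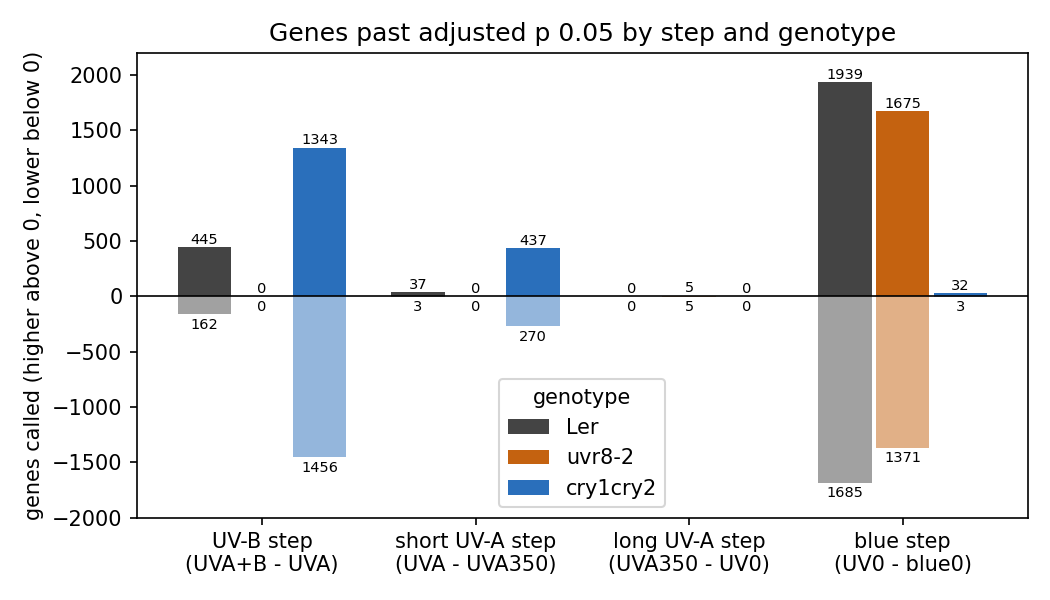
Number of genes called by edgeR (y axis, higher genes above 0 and lower genes below 0) for each step between neighbouring filters (x axis) in Ler, uvr8-2 and cry1cry2 (bar colours). At the UV-B step 607 genes were called in Ler, 0 in uvr8-2 and 2799 in cry1cry2, and at the blue step 3624, 3046 and 35.

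At the short UV-A step in Ler, MYB12 rose from 1.36 ± 0.083 to 16 ± 4.8 CPM (log2 3.55 ± 0.50), FLS1 from 118 ± 25 to 472 ± 100 CPM (2.00 ± 0.36), and 4CL3 (AT1G65060), a coumarate ligase gene, by 1.66 ± 0.25. GA2OX8 (AT4G21200), which encodes a gibberellin-inactivating oxidase, rose by 2.09 ± 0.29, and CRY3 (AT5G24850), a cryptochrome of the photolyase family, by 0.94 ± 0.15. CHS was not called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0744).

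Flavonoid enzyme genes rose in 7 of 24 cases in Ler at the short UV-A step (15 over the list alone, median 0.87, camera adjusted p = 8.5e-25, adjusted p = 0.0415 with an estimated correlation). Flavonoid regulators rose in 1 of 12 cases (3 over the list alone, camera adjusted p = 2.01e-07, adjusted p = 0.0225 with an estimated correlation). Sinapate ester genes rose in 1 of 5 cases (3 over the list alone, camera adjusted p = 2.83e-05, adjusted p = 0.0225 with an estimated correlation), namely FAH1 (0.67 ± 0.14). The UVR8-HY5 list had a median of 0.40 (0 of 18 called, 7 higher and 1 lower over the list alone, camera adjusted p = 2.27e-06, adjusted p = 0.11 with an estimated correlation). Heat shock genes had a median of 0.56 (0 of 10 called, 0 over the list alone, camera adjusted p = 0.00185, adjusted p = 0.11 with an estimated correlation). The median of flowering and floral organ markers was -0.32 (0 of 7 called, 0 over the list alone, camera adjusted p = 0.00108, adjusted p = 0.0415 with an estimated correlation), with 7 of 7 below 0. Photolyase and DNA damage genes had a median of 0.14 (1 of 16 higher, 3 higher over the list alone, camera adjusted p = 0.00149, adjusted p = 0.0639 with an estimated correlation). For jasmonate genes the median was 0.30 (0 of 24 called, 0 over the list alone, camera adjusted p = 0.00149, adjusted p = 0.636 with an estimated correlation). The median of shade and PIF targets was -0.33 (0 of 17 called, 0 over the list alone, camera adjusted p = 0.0141, adjusted p = 0.426 with an estimated correlation). In all 40 genes were called, 37 higher and 3 lower, and 96 by DESeq2. The count was 1 without Ler UVA replicate 1 or without Ler UVA350 replicate 1, 3 without Ler UVA350 replicate 2 and 23 without Ler UVA replicate 2, and none of the 15 called genes covered by the naming rule kept its call in each of these fits.

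In uvr8-2 none of these genes was called at the short UV-A step. MYB12 differed by 0.32 ± 0.56, FLS1 by 0.01 ± 0.35 and CHS by -0.14 ± 0.28. The 37 genes that rose in Ler had a median of 1.11 in Ler, where their choice raises it, and 0.17 in uvr8-2. The 437 genes that rose in cry1cry2, chosen from libraries that enter neither value, had a median of 0.36 in Ler and 0.09 in uvr8-2. edgeR called 0 genes (633 at an unadjusted p under 0.05, 0 by DESeq2, and 2 by edgeR without uvr8-2 UVA350 replicate 2). The difference from Ler was also called for 0 genes (685 at an unadjusted p under 0.05, 5 by DESeq2, and 1 by edgeR without uvr8-2 UVA350 replicate 2), with FLS1 at -1.99 ± 0.49 and MYB12 at -3.23 ± 0.77. Adjusted over the list alone, 16 of the 24 flavonoid enzyme genes had a lower response in uvr8-2 than in Ler (median difference -0.87, camera adjusted p = 6.52e-24, adjusted p = 0.0742 with an estimated correlation). For the same difference camera called flavonoid regulators (-0.59, 0 of 12, 1 lower over the list alone), sinapate ester genes (-0.34, 0 of 5, 1 lower over the list alone), UVR8-HY5 genes (-0.32), photolyase and DNA damage genes (-0.15, 0 of 16, 1 lower over the list alone), light harvesting and Rubisco genes (-0.14), heat shock genes (-0.52), shade and PIF targets (0.29) and auxin response genes (0.36), each with its median difference. Each had a camera adjusted p = 1.73e-05 to 0.0499, with adjusted p = 0.0742 to 0.575 with an estimated correlation.

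At the short UV-A step in cry1cry2, ELIP2 (AT4G14690) rose by 5.06 ± 0.68, ELIP1 by 3.97 ± 0.45, FLS1 from 23.1 ± 5.6 to 357 ± 110 CPM (3.95 ± 0.40), and GPX7 (AT4G31870), which encodes a glutathione peroxidase, from 9.67 ± 0.11 to 95.5 ± 5.4 CPM (3.30 ± 0.25). YUC8 (AT4G28720), an auxin synthesis gene, fell by 2.09 on the log2 scale (SE 0.44), and the defence regulator gene NIMIN1 (AT1G02450) by 1.76 (SE 0.29). Flavonoid enzyme genes rose in 14 of 24 cases (17 over the list alone, camera adjusted p = 2.56e-26, adjusted p = 0.0371 with an estimated correlation). UVR8-HY5 genes rose in 8 and fell in 1 of 18 cases (10 and 1 over the list alone, camera adjusted p = 6.37e-11, adjusted p = 0.0371 with an estimated correlation). Salicylate defence genes fell in 2 of 20 cases, NIMIN1 and WRKY70 (-0.76 ± 0.20; 3 over the list alone, camera adjusted p = 0.0177, adjusted p = 0.57 with an estimated correlation). Sinapate ester genes had a median of 0.89 (3 of 5 higher, 3 higher over the list alone, camera adjusted p = 1.89e-05, adjusted p = 0.0221 with an estimated correlation). For flavonoid regulators the median was 0.68 (3 of 12 higher, 5 higher over the list alone, camera adjusted p = 1.89e-05, adjusted p = 0.0371 with an estimated correlation). The median of photolyase and DNA damage genes was 0.19 (3 of 16 higher, 3 higher over the list alone, camera adjusted p = 0.000473, adjusted p = 0.0371 with an estimated correlation). Camera also called shade and PIF targets (-0.29, 1 lower of 17, 1 lower over the list alone), heat shock genes (0.55, 0 of 10, 3 higher over the list alone) and aliphatic glucosinolate genes (0.13), each with its median. They had a camera adjusted p = 0.0281 to 0.0468, with adjusted p = 0.382 to 0.478 with an estimated correlation. Without each library in turn, YUC8 and WRKY70 lost the call at least once and the other genes named did not.

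The short UV-A step called 707 genes in cry1cry2, 437 higher and 270 lower, and 33 of the higher ones were also higher in Ler against 0.8 for independent lists. The difference from Ler was called for 3 genes, GPX7 (2.25 ± 0.32), AT1G57770 (1.34 ± 0.21) and SPPA (AT1G73990, 1.23 ± 0.20), a plastid protease gene, with 751 at an unadjusted p under 0.05 and 23 by DESeq2. For the difference from Ler, camera called flavonoid enzyme genes (0.42, 0 of 24, 2 higher over the list alone), UVR8-HY5 genes (0.35, 1 higher of 18, 4 higher over the list alone) and aliphatic glucosinolate genes (0.18), each with its median difference. These had a camera adjusted p = 6.04e-07 to 0.0012, with adjusted p = 0.313 to 0.441 with an estimated correlation. The count was 0 without Ler UVA replicate 1, Ler UVA replicate 2, Ler UVA350 replicate 1, Ler UVA350 replicate 2, cry1cry2 UVA replicate 1, cry1cry2 UVA350 replicate 1 or cry1cry2 UVA replicate 2, and 0 without the 3 libraries of over 1% chloroplast counts. Without cry1cry2 UVA350 replicate 2 it was 3, with 2 of the same genes, so GPX7 lost the call in 8 of 8 fits and AT1G57770 and SPPA in 7. The count within cry1cry2 was 310 without UVA replicate 1 (83 lower), 283 without UVA350 replicate 1 (67 lower), 362 without UVA replicate 2 (49 lower) and 444 without UVA350 replicate 2 (129 lower). It was 373 (71 lower) without the 3 libraries of over 1% chloroplast counts.

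At the long UV-A step in Ler, CHS (-0.29 ± 0.28), HY5 (0.53 ± 0.25) and ELIP1 (-0.02 ± 0.39) were not called, and edgeR called 0 genes (919 at an unadjusted p under 0.05, 3 by DESeq2). Salicylate defence genes in Ler had a median of -0.44 (0 of 20 called, 0 over the list alone, camera adjusted p = 1.94e-06, adjusted p = 0.53 with an estimated correlation). Flavonoid enzyme genes in Ler had a median of -0.24 (0 of 24 called, 0 over the list alone, camera adjusted p = 0.00456, adjusted p = 0.53 with an estimated correlation). Small positive medians were called by camera for light harvesting and Rubisco genes (0.10, 0 of 20 called, adjusted p = 0.0172), chlorophyll synthesis genes (0.13, 0 of 11, adjusted p = 0.0424) and aliphatic glucosinolate genes (0.05, 0 of 13, adjusted p = 0.0424). In each of these lists 0 genes were called over the list alone, and camera gave an adjusted p = 0.53 with an estimated correlation. In uvr8-2, CYP98A3 (AT2G40890), a hydroxylase gene of phenylpropanoid synthesis, rose from 32.8 ± 0.56 to 47.2 ± 0.94 CPM (0.52 ± 0.09), and MIOX1 (AT1G14520), an inositol oxygenase gene, fell from 33 ± 3.4 to 14.5 ± 3.1 CPM (-1.19 ± 0.21). FBA5 (AT4G26530), an aldolase gene, rose by 1.04 ± 0.19. Jasmonate genes in uvr8-2 had a median of -0.55 (0 of 24 called, 0 over the list alone, camera adjusted p = 2.01e-06, adjusted p = 0.79 with an estimated correlation). Light harvesting and Rubisco genes had a median of 0.25 (0 of 20 called, 4 higher over the list alone, camera adjusted p = 2.73e-05, adjusted p = 0.79 with an estimated correlation). Salicylate defence genes had a median of -0.35 (0 of 20 called, 0 over the list alone, camera adjusted p = 0.00281, adjusted p = 0.836 with an estimated correlation). Chlorophyll synthesis genes had a median of 0.30 (0 of 11 called, 1 higher over the list alone, camera adjusted p = 0.00473, adjusted p = 0.619 with an estimated correlation).

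In uvr8-2 10 genes were called at the long UV-A step, 5 higher and 5 lower (3086 at an unadjusted p under 0.05, 263 by DESeq2). The count was 0 without uvr8-2 UVA350 replicate 1, 1 without uvr8-2 UV0 replicate 1, 19 without uvr8-2 UVA350 replicate 2, 76 without uvr8-2 UV0 replicate 2, 16 without the 3 libraries of over 1% chloroplast counts, and 0 with only uvr8-2 libraries in the fit, so none of the genes named kept its call throughout. In cry1cry2 edgeR called 0 genes (610 at an unadjusted p under 0.05, 1 by DESeq2, and 3 by edgeR without cry1cry2 UV0 replicate 1). There the flavonoid enzyme list had a median of -0.52 (0 of 24 called, 4 lower over the list alone, camera adjusted p = 2.62e-14, adjusted p = 0.421 with an estimated correlation). Camera also called the salicylate defence list (median -0.23, 0 of 20 called, adjusted p = 0.00443, adjusted p = 0.576 with an estimated correlation) and the UVR8-HY5 list (-0.09, 0 of 18, adjusted p = 0.0202, adjusted p = 0.576 with an estimated correlation). It called the flavonoid regulators (-0.30, 0 of 12) and the heat shock list (0.44, 0 of 10), each at a camera adjusted p = 0.0223 and adjusted p = 0.421 with an estimated correlation. In these 4 lists 0 genes were called over the list alone. The difference from Ler was called by edgeR for 0 genes in uvr8-2 (566 at an unadjusted p under 0.05, 0 by DESeq2, and 1 without uvr8-2 UVA350 replicate 2) and for 0 in cry1cry2 (291 at an unadjusted p under 0.05, 0 by DESeq2, and 1 without cry1cry2 UV0 replicate 1). For the difference of uvr8-2 from Ler, camera called jasmonate genes (-0.35), light harvesting and Rubisco genes (0.17) and aliphatic glucosinolate genes (-0.12), each with its median difference. Each had a camera adjusted p = 0.00244 to 0.0471, with adjusted p = 0.762 with an estimated correlation. For that of cry1cry2 it called aliphatic glucosinolate genes (-0.18), UVR8-HY5 genes (-0.15), flavonoid enzyme genes (-0.33) and flowering and floral organ markers (-0.48), each with its median difference. They had a camera adjusted p = 0.000545 to 0.00578, with adjusted p = 0.322 to 0.584 with an estimated correlation.

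**Figure D2:**
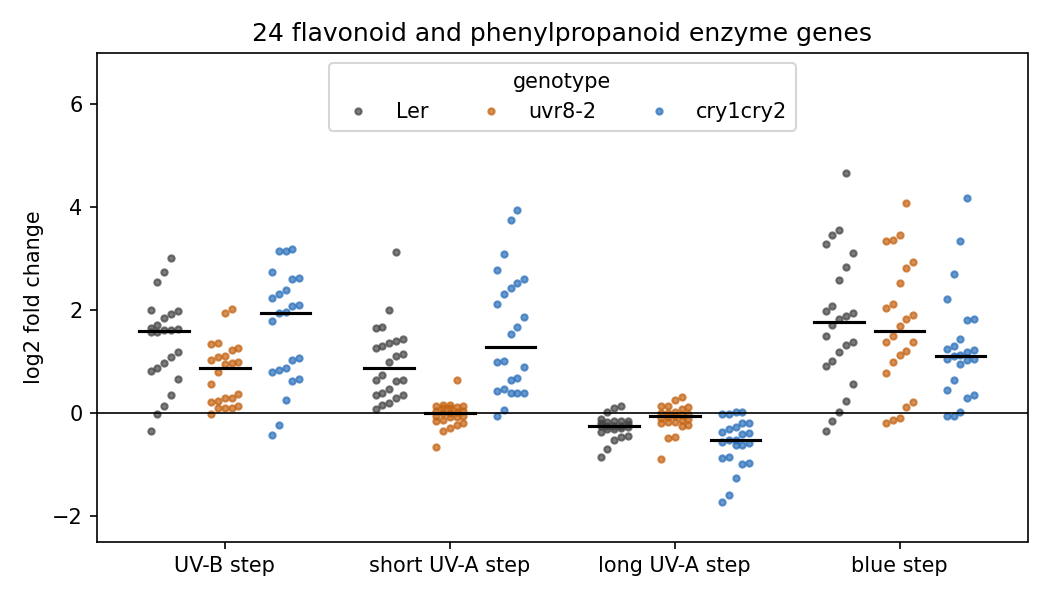
Log2 fold change (y axis) of the 24 flavonoid and phenylpropanoid enzyme genes (points) at each step (x axis) in Ler, uvr8-2 and cry1cry2 (colours), with the median of each group as a black line. The medians at the UV-B step are 1.59 in Ler, 0.88 in uvr8-2 and 1.95 in cry1cry2.

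At the blue step in Ler, ELIP1 rose from 2.02 ± 0.4 to 515 ± 120 CPM (log2 7.99 ± 0.57), ELIP2 from 0.199 ± 0.028 to 144 ± 16 CPM (9.44 ± 1.02) and GPX7 from 2.24 ± 0.47 to 52.3 ± 4.6 CPM (4.53 ± 0.29). CHS rose from 97.8 ± 5.6 to 844 ± 180 CPM (3.11 ± 0.30), and HY5 (AT5G11260) and HYH (AT3G17609), which promote light responses, by 1.73 ± 0.28 and 2.32 ± 0.36. MYB12 held 2 counts under blue0 and 68 under UV0, a ratio of 40 (95% counting interval 10.7 to 337). Genes that fell included PORA (AT5G54190), a chlorophyll synthesis gene of dark-grown tissue (12.2 ± 3.4 to 1.71 ± 0.72 CPM, -2.89 ± 0.50), and the cell wall genes XTH33 (AT1G10550, -3.39 ± 0.54) and XTH15 (AT4G14130, -2.54 ± 0.42). CIB1 (AT4G34530), which encodes a partner of cryptochrome 2, held 1 count under UV0 and 471 under blue0, a ratio of 400 (95% counting interval 71.4 to 15800).

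Flavonoid enzyme genes rose in 20 of 24 cases at the blue step in Ler (20 over the list alone, median 1.78, camera adjusted p = 3.28e-18, adjusted p = 0.111 with an estimated correlation). UVR8-HY5 genes rose in 10 and fell in 1 of 18 cases (11 and 1 over the list alone, camera adjusted p = 6.68e-10, adjusted p = 0.111 with an estimated correlation). Shade and PIF targets fell in 9 of 17 cases (11 over the list alone, median -0.86, camera adjusted p = 1.09e-05, adjusted p = 0.116 with an estimated correlation), with PIF4 at -1.07 ± 0.13 and PIF3 at -0.64 ± 0.13. Auxin response genes fell in 6 of 14 cases (9 over the list alone, camera adjusted p = 0.00115, adjusted p = 0.44 with an estimated correlation), with IAA2 at -1.08 ± 0.19 and IAA19 at -1.40 ± 0.35. Camera also called flavonoid regulators (median 0.94, 9 higher of 12, 9 higher over the list alone). This had a camera adjusted p = 0.000156, with adjusted p = 0.111 with an estimated correlation. BIC1 (1.34 ± 0.21) and BIC2 (0.88 ± 0.16), inhibitors of the cryptochromes, rose, while CRY1 itself fell (-0.53 ± 0.11). Counts without each library in turn ran from 1655 (Ler blue0 replicate 1) through 1683 (Ler UV0 replicate 2) and 2174 (Ler UV0 replicate 1) to 2323 (Ler blue0 replicate 2), against 3624 with all, 1939 higher and 1685 lower. MYB12, IAA19 and CRY1 lost the call in at least 1 of these fits, and the other genes named for this step did not.

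In uvr8-2 the blue step raised ELIP1 by 7.89 ± 0.55, CHS by 2.93 ± 0.30, GPX7 by 4.11 ± 0.29 and HY5 by 1.33 ± 0.27. Flavonoid enzyme genes rose in 19 of 24 cases (19 over the list alone, camera adjusted p = 6.82e-19, adjusted p = 0.0841 with an estimated correlation). Circadian clock genes rose in 2 of 16 cases, GI (0.81 ± 0.17) and PRR7 (0.43 ± 0.09), with a camera adjusted p = 0.017 (2 over the list alone, adjusted p = 0.0841 with an estimated correlation). Further lists called by camera were UVR8-HY5 genes (1.24, 12 higher and 1 lower of 18, 13 higher and 1 lower over the list alone), flavonoid regulators (1.29, 8 higher of 12, 8 higher over the list alone), shade and PIF targets (-0.52, 6 lower of 17, 8 lower over the list alone) and auxin response genes (-0.92, 4 lower of 14, 9 lower over the list alone), each with its median. Each had a camera adjusted p = 2.96e-11 to 0.00291, with adjusted p = 0.0841 to 0.52 with an estimated correlation. In all 3046 genes were called, 1675 higher and 1371 lower, and 1181 of the higher ones were also higher in Ler against 162.6 for independent lists. The difference from Ler was called by edgeR for 0 genes (665 at an unadjusted p under 0.05, 0 by DESeq2), with CHS at -0.18 ± 0.40 and ELIP1 at -0.10 ± 0.69. Called by camera as well were light harvesting and Rubisco genes (median difference -0.19). This had a camera adjusted p = 0.0065, with adjusted p = 0.909 with an estimated correlation. The count in uvr8-2 was 1839 without UV0 replicate 2, 1649 without blue0 replicate 2, 1559 without the 3 libraries of over 1% chloroplast counts and 1382 with only uvr8-2 libraries in the fit.

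At the blue step in cry1cry2, ELIP1 rose from 2.46 ± 1.5 to 100 ± 58 CPM (5.39 ± 0.52) and GPX7 from 0.95 ± 0.019 to 15.8 ± 9.6 CPM (4.06 ± 0.33). CHS rose by 2.22 ± 0.29 and FLS1 by 3.35 ± 0.41, and EBF2 (AT5G25350), an ethylene signalling gene, and BES1 (AT1G19350), a brassinosteroid regulator, fell (-0.76 ± 0.12 and -0.60 ± 0.12). Flavonoid enzyme genes rose in 6 of 24 cases (19 over the list alone, median 1.12, camera adjusted p = 1.73e-33, adjusted p = 0.0455 with an estimated correlation). UVR8-HY5 genes rose in 4 of 18 cases (7 higher and 1 lower over the list alone, camera adjusted p = 2.45e-11, adjusted p = 0.047 with an estimated correlation). For flavonoid regulators the median was 0.88 (0 of 12 called, 5 higher over the list alone, camera adjusted p = 5.27e-06, adjusted p = 0.047 with an estimated correlation). As sets, camera also called sinapate ester genes (0.25, 1 higher of 5, 1 higher over the list alone), auxin response genes (-0.46), shade and PIF targets (-0.25, 0 of 17, 1 lower over the list alone), aliphatic glucosinolate genes (0.09) and flowering and floral organ markers (0.38), each with its median. These had a camera adjusted p = 0.00617 to 0.0419, with adjusted p = 0.107 to 0.454 with an estimated correlation. In all 35 genes were called, 32 higher and 3 lower (99 by DESeq2). Of these, 32 and 3 were called the same way in Ler, against 3.1 and 0.3 for independent lists. The 1939 genes that rose in Ler had a median of 0.64 in Ler, where their choice raises it, and 0.21 in cry1cry2. The 1675 genes that rose in uvr8-2, chosen from libraries that enter neither value, had a median of 0.61 in Ler and 0.18 in cry1cry2. The count of 35 became 53 without cry1cry2 UV0 replicate 1, 4 without cry1cry2 blue0 replicate 1, 3 without cry1cry2 UV0 replicate 2, 4 without cry1cry2 blue0 replicate 2, and 5 with only cry1cry2 libraries in the fit, and of the genes named here ELIP1 and GPX7 alone stayed called without each library in turn.

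The difference of the blue step between cry1cry2 and Ler was called for 109 genes, 21 higher and 88 lower in cry1cry2. FAD8 (AT5G05580), a plastid fatty acid desaturase gene, stood at 56.8 ± 5.4 and 213 ± 2.3 CPM in Ler under blue0 and UV0, and at 81.6 ± 7.3 and 110 ± 15 CPM in cry1cry2 (difference -1.47 ± 0.18). GLDP1 (AT4G33010), which encodes a photorespiratory glycine decarboxylase subunit, had a difference of -1.51 ± 0.29, and LHCB4.3 (AT2G40100), an antenna gene, of -1.65 ± 0.27. HY5 (-0.96 ± 0.38), CHS (-0.89 ± 0.40) and ELIP1 (-2.59 ± 0.73) were not called. UVR8-HY5 genes were lower in 1 of 18 cases, WAKL8 (-1.33 ± 0.26; 5 lower and 1 higher over the list alone, camera adjusted p = 2.36e-05, adjusted p = 0.472 with an estimated correlation). Shade and PIF targets had a median difference of 0.53 (0 of 17 called, 4 higher over the list alone, camera adjusted p = 0.000208, adjusted p = 0.472 with an estimated correlation). Camera also called flavonoid enzyme genes (median difference -0.46, 0 of 24, 1 lower over the list alone). This had a camera adjusted p = 5.79e-05, with adjusted p = 0.692 with an estimated correlation. DESeq2 called 350 genes. The count of 109 became 20 without Ler UV0 replicate 1 (2 higher), 2 without Ler blue0 replicate 1 (0 higher), 19 without Ler UV0 replicate 2 (1 higher), 1 without cry1cry2 UV0 replicate 1 (0 higher), 60 without cry1cry2 blue0 replicate 1, 57 without cry1cry2 UV0 replicate 2 and 30 without cry1cry2 blue0 replicate 2. FAD8 stayed called in each of these fits, and GLDP1, LHCB4.3 and WAKL8 did not.

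**Figure D3:**
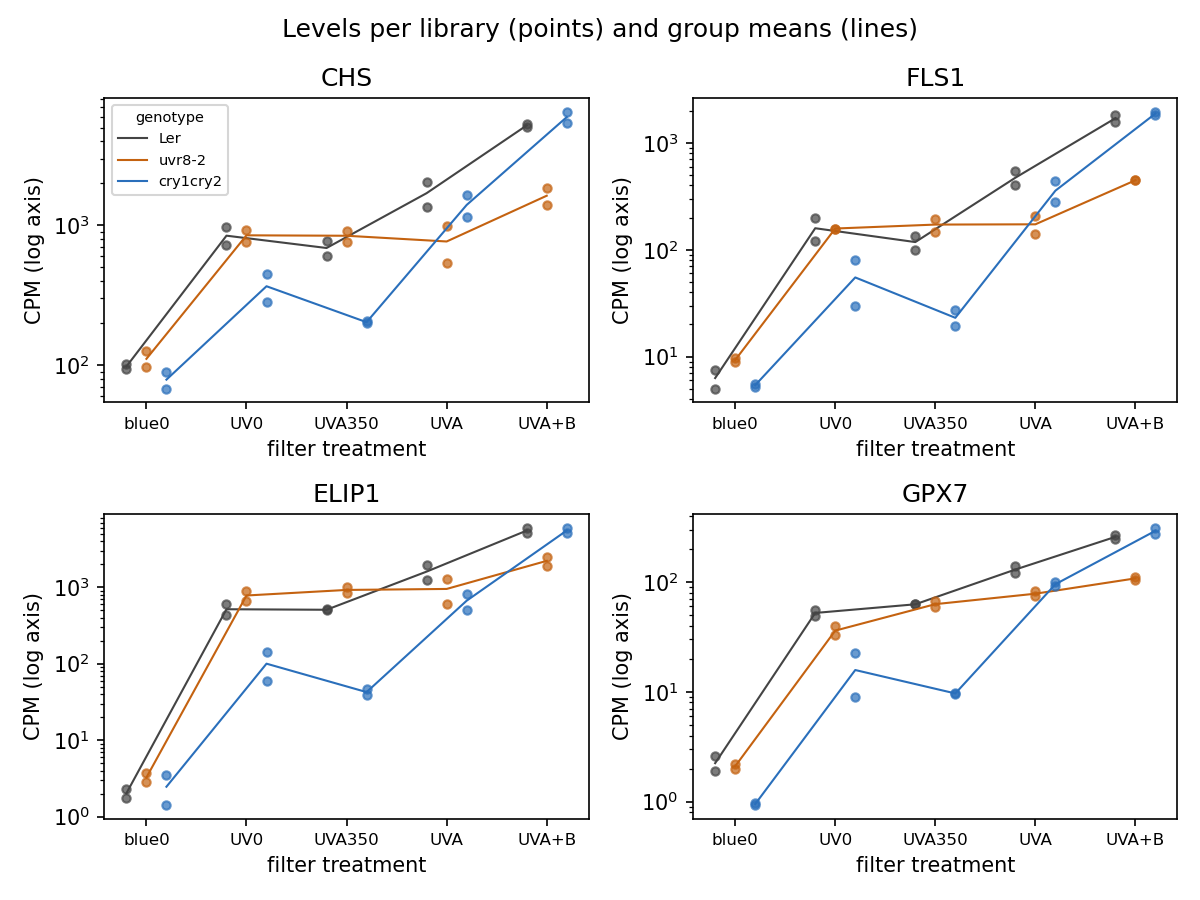
CPM on a log axis (y axis) of CHS, FLS1, ELIP1 and GPX7 under each filter (x axis), with 1 point per library and lines through the group means of Ler, uvr8-2 and cry1cry2 (colours). CHS under UVA+B stands at 5190 CPM in Ler, 1630 in uvr8-2 and 5950 in cry1cry2.

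Under UVA+B, CHS was lower in uvr8-2 than in Ler by -1.67 ± 0.29, GSTF12 (AT5G17220), an anthocyanin transport gene, by -2.13 ± 0.21, UVR3 by -2.98 ± 0.36 and AT1G64340 by -4.34 ± 0.30. AT5G24130 held 3 counts in uvr8-2 and 223 in Ler, a ratio of 78.6 (95% counting interval 26.6 to 384). CSD1 (-0.80 ± 0.17) and CSD2 (-1.09 ± 0.19), which encode copper and zinc superoxide dismutases, and their chaperone gene CCS were lower too. IAA29 (2.44 ± 0.52), IAA19 (1.80 ± 0.43) and MYB28 (AT5G61420, 0.63 ± 0.12), a glucosinolate regulator, were higher.

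Flavonoid enzyme genes were lower in uvr8-2 in 21 of 24 cases and higher in 1 under UVA+B (21 and 1 over the list alone, median -1.71, camera adjusted p = 4.49e-19, adjusted p = 0.124 with an estimated correlation). Reactive oxygen genes were lower in 5 of 10 cases (5 lower and 1 higher over the list alone, camera adjusted p = 0.0298, adjusted p = 0.202 with an estimated correlation). Auxin response genes were higher in 4 of 14 (7 over the list alone, camera adjusted p = 0.000515, adjusted p = 0.285 with an estimated correlation). Aliphatic glucosinolate genes were higher in 7 of 13 (7 over the list alone, camera adjusted p = 0.00193, adjusted p = 0.229 with an estimated correlation). Flowering and floral organ markers were higher in 3 of 7, SVP, SEP3 and AG (3 over the list alone, camera adjusted p = 0.0274, adjusted p = 0.202 with an estimated correlation). Further lists called by camera were flavonoid regulators (-0.90, 8 lower of 12, 9 lower over the list alone), sinapate ester genes (-0.71, 3 lower of 5, 1 higher and 3 lower over the list alone), photolyase and DNA damage genes (-0.16, 4 lower of 16, 5 lower over the list alone), UVR8-HY5 genes (-0.44, 1 higher and 7 lower of 18, 2 higher and 9 lower over the list alone), shade and PIF targets (0.46, 2 higher of 17, 4 higher over the list alone), light harvesting and Rubisco genes (0.33, 2 higher of 20, 6 higher and 1 lower over the list alone) and jasmonate genes (-0.60, 4 lower of 24, 6 lower over the list alone), each with its median difference. They had a camera adjusted p = 4.7e-05 to 0.0251, with adjusted p = 0.124 to 0.577 with an estimated correlation. In all 3034 genes were called, 1356 higher and 1678 lower. The count was 662 without uvr8-2 UVA+B replicate 1 and 867 without Ler UVA+B replicate 2. Of 60 called genes covered by the naming rule, 35 stayed called without each library in turn, CHS, GSTF12, UVR3, CSD1, CSD2 and CCS among them, and IAA29, IAA19, MYB28, SVP, SEP3 and AG did not.

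Under blue0, uvr8-2 and Ler gave 0 calls with edgeR (1130 at an unadjusted p under 0.05, 13 by DESeq2). The count became 1 without Ler blue0 replicate 1 and 9 without uvr8-2 blue0 replicate 1. Light harvesting and Rubisco genes had a median difference of 0.18 (0 of 20 called, 0 over the list alone, camera adjusted p = 4.3e-05, adjusted p = 0.619 with an estimated correlation). The library with 1.585% chloroplast counts, uvr8-2 blue0 replicate 2, is in this comparison, and whether it bears on the list was not tested. In comparisons chosen after the data were seen, the median difference was also 0.18 under UVA350 (0 of 20 called, camera adjusted p = 0.00531, adjusted p = 0.796 with an estimated correlation). No UVA350 library had over 1% chloroplast counts. Under UVA the median difference was 0.03 and under UV0 -0.01. The aliphatic glucosinolate list had a median difference of 0.15 (0 of 13 called, 1 higher over the list alone, camera adjusted p = 0.00837, adjusted p = 0.619 with an estimated correlation). Called by camera as well were salicylate defence genes (median difference -0.30). This had a camera adjusted p = 0.01, with adjusted p = 0.732 with an estimated correlation.

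Under UVA+B, the late anthocyanin enzyme genes DFR (-1.25 ± 0.22), LDOX (-1.29 ± 0.23), UGT75C1 (-1.32 ± 0.25) and UGT79B1 (-1.21 ± 0.21) were lower in cry1cry2 than in Ler, as were CSD2 (-1.30 ± 0.19) and CCS (-1.10 ± 0.22). MAF5 (AT5G65080), a flowering repressor gene, stood at 0.191 ± 0.19 CPM against 10.2 ± 0.79 CPM in Ler, and MRD1 (AT1G53480) at 0.707 ± 0.54 against 24.3 ± 1.2 CPM. SADHU3-2 (AT3G42658), a retroposon, held 0 counts in cry1cry2 and was at least 79.3-fold lower than in Ler, from a floor of 3 counts over the group. WSD1 (AT5G37300), a wax ester synthase gene, was higher by 1.93 ± 0.38.

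Flavonoid enzyme genes were lower in cry1cry2 in 4 of 24 cases under UVA+B (6 over the list alone, camera adjusted p = 0.00878, adjusted p = 0.683 with an estimated correlation). Jasmonate genes were lower in 2 of 24 (12 over the list alone, median -0.89, camera adjusted p = 4.17e-10, adjusted p = 0.393 with an estimated correlation), VSP1 (-2.42 ± 0.51) and AOC2 (-0.90 ± 0.20). As sets, camera also called light harvesting and Rubisco genes (-0.19, 1 lower of 20, 2 lower over the list alone), photolyase and DNA damage genes (0.16), heat shock genes (0.67), reactive oxygen genes (-0.24, 2 lower of 10, 3 lower over the list alone) and guard cell and phloem markers (0.19, 0 of 6, 2 higher over the list alone), each with its median difference. Each had a camera adjusted p = 0.00609 to 0.0363, with adjusted p = 0.393 to 0.561 with an estimated correlation. In all 172 genes were called, 60 higher and 112 lower (263 by DESeq2). The count was 35 without Ler UVA+B replicate 1 (16 higher, 19 lower), 35 without cry1cry2 UVA+B replicate 1 (21 higher, 14 lower) and 54 without cry1cry2 UVA+B replicate 2 (24 higher, 30 lower). It was 223 without Ler UVA+B replicate 2 (41 higher, 182 lower) and 67 without the 3 libraries of over 1% chloroplast counts. MAF5, MRD1 and SADHU3-2 stayed called without each library in turn, and the other genes named for this comparison did not.

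Under blue0, cry1cry2 still differed from Ler. SADHU3-2 was at least 156-fold lower (0 counts in cry1cry2), and MRD1 (-4.28 ± 0.25) and MAF5 (-4.20 ± 0.39) were lower, while HY5 (1.27 ± 0.28), WSD1 (2.41 ± 0.36) and the defence genes NIMIN1 (1.22 ± 0.27) and WRKY70 (0.97 ± 0.20) were higher. Salicylate defence genes were higher in 3 of 20 cases (8 over the list alone, median 0.36, camera adjusted p = 8.34e-05, adjusted p = 0.627 with an estimated correlation). Jasmonate genes were lower in 1 of 24, VSP1 (-2.62 ± 0.52; 4 over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.627 with an estimated correlation). Guard cell and phloem markers had a median difference of 0.31 (0 of 6 called, 2 higher over the list alone, camera adjusted p = 0.02, adjusted p = 0.512 with an estimated correlation). Camera also called flavonoid enzyme genes (-0.30, 2 lower of 24, 1 higher and 4 lower over the list alone) and UVR8-HY5 genes (0.24, 2 higher of 18, 5 higher and 1 lower over the list alone), each with its median difference. They had a camera adjusted p = 0.000806 to 0.00338, with adjusted p = 0.627 to 0.747 with an estimated correlation. In all 301 genes were called, 185 higher and 116 lower (497 by DESeq2). The count was 115 without Ler blue0 replicate 1 (58 higher, 57 lower), 96 without cry1cry2 blue0 replicate 1, 95 without Ler blue0 replicate 2 and 64 without cry1cry2 blue0 replicate 2. MRD1, MAF5, SADHU3-2 and WSD1 stayed called without each library in turn, and HY5, NIMIN1, WRKY70 and VSP1 did not.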

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

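Of the tests below, those of replicate spread and of depth were chosen after the results were seen, as were the comparisons of total UV (UVA+B minus UV0), which were not planned. The differences in the next pair of paragraphs passed an adjusted p of 0.05 in edgeR's test of the difference between genotypes. The patterns weighed after them were chosen from counts of calls.

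At the UV-B step the response of uvr8-2 differed from that of Ler for 1 gene, RAD52-2 (-1.29), and at the short UV-A step the response of cry1cry2 differed for 3 genes, GPX7 (2.25), AT1G57770 (1.34) and SPPA (1.23). Without each library in turn, RAD52-2 kept its call in 8 of 8 fits, while GPX7 lost it in 8 and AT1G57770 and SPPA in 7. At the blue step 109 genes differed between cry1cry2 and Ler. The largest differences were higher for AT1G47606 (1.94), AT1G25230 (1.67), AT5G57340 (1.26), AT1G51400 (1.09) and TRM3 (1.06), and lower for AT5G55570 (-1.78), LHCB4.3 (-1.65), PDX1.1 (-1.65), GLDP1 (-1.51) and FAD8 (-1.47), with WAKL8 at -1.33. Of these genes FAD8 alone kept its call in 8 of 8 fits without 1 library, and the others lost it in 2 (AT5G55570) to 7 (AT1G47606, AT1G25230 and GLDP1) of 8.

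For total UV, 133 genes differed between uvr8-2 and Ler, with AT5G02760 (2.30), ACS4 (2.05), EXPA11 (1.55), P1R1 (1.54) and ATSPS4F (1.41) at the upper end and AT3G24750 (-4.00), AT3G20370 (-3.28), AT1G30190 (-3.26), AT5G62210 (-3.14) and UVR3 (-2.81) at the lower end. Between cry1cry2 and Ler 13 genes differed, among them GPX7 (1.90), AT1G76720 (1.85), AT1G06690 (1.67), AT1G57770 (1.49), SPPA (1.29), AT1G23390 (-1.68), CSLB04 (-1.36), PSAD-2 (-1.33), AT5G57340 (-1.26) and PETE1 (-0.88).

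The UV-B step gave 607 calls in Ler and 0 by edgeR in uvr8-2 (1204 at an unadjusted p under 0.05, 37 by DESeq2). A larger spread in uvr8-2 hiding responses of Ler's size is argued against for the 1343 genes that rose in cry1cry2, as a set. These genes, chosen from libraries that enter neither value, had a median of 0.10 in uvr8-2 and 0.38 in Ler. In fits without 1 library the uvr8-2 median ran from 0.06 to 0.16, below Ler in 8 of 8. Over all filters, the median absolute log2 difference between replicates was 0.205 in uvr8-2 and 0.168 in Ler. For single genes a larger spread may still hide a response. Lower depth is argued against, since the uvr8-2 libraries of the step had 98.8% of the mean total of those of Ler. Loss of UVR8 function stays open as a biological hypothesis. The direct test of the difference called 1 gene, but such a test misses many changes. On simulated counts with 200 genes changed, the same kind of test between cry1cry2 and Ler recovered 30.8% of genes changed 2-fold. That share need not hold for uvr8-2, where the number of genes that differ is not known. Against Ler, uvr8-2 gave 0 calls by edgeR under blue0 and 3034 under UVA+B. The response to total UV differed from that of Ler for 133 genes, 111 of them lower in uvr8-2.

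The UV-B step gave 2799 calls in cry1cry2 and 607 in Ler, with 0 genes called for the difference. Carry-over of RNA without poly(A) in the 2 cry1cry2 libraries of over 1% chloroplast counts is argued against for the 445 genes that rose in Ler. Without these libraries their median was 0.87 in cry1cry2, against 0.75 in Ler with all libraries. For the other genes called in cry1cry2 carry-over stays open, since that median does not cover them. Their number of calls cannot decide it, because leaving out these libraries leaves 1 library in each cry1cry2 group of the step. A smaller spread in cry1cry2 with responses of the same size is argued against for the 445 genes, whose median with all libraries was 0.91 in cry1cry2 and 0.75 in Ler, where their choice raises it, and in fits without 1 library 0.82 to 0.98 in cry1cry2, above Ler by more than 0.05 in 8 of 8. For other genes a smaller spread stays open, as the median difference between the libraries of a group was 0.149 (UVA+B) and 0.179 (UVA) in cry1cry2 and 0.194 and 0.167 in Ler. The 2 genotypes did not start the step at the same levels. Against Ler, cry1cry2 gave 675 calls under UVA, in a comparison chosen after the data were seen, and 172 under UVA+B. Under UVA, 9 of 24 flavonoid enzyme genes were lower in cry1cry2 and 0 higher (median difference -0.57). What the starting level adds to the count of calls was not tested. Loss of the cryptochromes stays open as an untested hypothesis.

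Under blue0, 301 genes differed between cry1cry2 and Ler. Segments of another parent linked to CRY1 or CRY2 are argued against as the main source: 2.7% of the genes (8 of 301, exact 95% interval 1.2% to 5.2%) lay within 100 tested genes of CRY1 or CRY2, against 2.0% of all tested genes. A constant difference unrelated to light stays open: 72.4% of the genes (218 of 301, 67.0% to 77.4%) had the same sign under all 4 other filters, between the bounds set for and against it. A share of 6.2% would arise if the signs under the 4 filters were independent. A difference shared by these filters raises that share whatever its cause, so 6.2% is too low a reference. The filters share no libraries with blue0. MAF5, MRD1 and SADHU3-2 were called lower in cry1cry2 under UVA+B and blue0. They were also called lower under UVA, UVA350 and UV0, in comparisons chosen after the data were seen. Under these filters MAF5 differed by -5.26 to -4.87 and MRD1 by -5.07 to -4.13. For these genes the difference was thus present under all 5 filters. They are among the largest differences and do not decide the question for the other genes. A role of the cryptochromes in the remaining light stays open and was not tested.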

How the results depend on the processing

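Leaving out together the libraries of over 1% chloroplast counts was chosen after the data were seen; the other alternatives were not. Direction was followed for the named genes and the gene lists only, and no called value among these changed direction under any alternative. For camera with an estimated correlation, the direction was that of the main test. RLE size factors moved no count of calls by over 1.5 times. Where a count moved the cause was not tested, except that leaving out libraries leaves fewer samples.

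Without the filter on low counts, the counts of calls were 6 (UV-B step in uvr8-2), 38 (long UV-A step in uvr8-2), 3 (difference of uvr8-2 at the UV-B step), 1 (difference of cry1cry2 at the UV-B step), 5 (difference of cry1cry2 at the short UV-A step) and 1 (uvr8-2 against Ler under blue0). DESeq2 called 96 and 3 genes in Ler at the short and long UV-A steps, 37 and 263 in uvr8-2 at the UV-B and long UV-A steps, and 1 and 99 in cry1cry2 at the long UV-A and blue steps. For differences from Ler, DESeq2 called 27 and 5 in uvr8-2 at the UV-B and short UV-A steps, and 1, 23 and 350 in cry1cry2 at the UV-B, short UV-A and blue steps. For genotypes it called 13 (uvr8-2, blue0), 263 (cry1cry2, UVA+B) and 497 (cry1cry2, blue0). With only the libraries of 1 genotype in the fit, the counts were 1 (Ler, long UV-A), 0 (uvr8-2, long UV-A), 1382 (uvr8-2, blue) and 5 (cry1cry2, blue). Without the libraries of over 1% chloroplast counts, they were 16 (uvr8-2, long UV-A), 1559 (uvr8-2, blue), 616 (cry1cry2, UV-B), 373 (cry1cry2, short UV-A), 0 (difference of cry1cry2, short UV-A) and 67 (cry1cry2 against Ler, UVA+B).

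Libraries with the same number deviated together in part: over the 105 pairs of groups, the correlation of their deviations from the group means ran from 0.03 to 0.43 (median 0.18) and was over 0.1 in 92. It ran from 0.11 to 0.26 between neighbouring filters of 1 genotype, and all 15 groups had a positive mean correlation with the rest. The third principal component (6.5% of the variance) split the numbers the same way in 15 of 15 groups. This is a hint from the data of a shared source. The labels do not say that a number marks the same field blocks in every group, so the block was not taken as part of the design. With the replicate block the counts were 1246, 149 and 1 in Ler (UV-B, short and long UV-A), 22 and 812 in uvr8-2 (UV-B, long UV-A), and 4364, 1798 and 121 in cry1cry2 (UV-B, short UV-A, blue). With the block the differences from Ler gave 18 (uvr8-2, UV-B), 10 (cry1cry2, short UV-A) and 503 (cry1cry2, blue), and the genotypes 4672 and 10 (uvr8-2, UVA+B and blue0) and 490 and 1073 (cry1cry2, UVA+B and blue0).

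Without each library in turn, counts in Ler ran from 119 to 563 (UV-B), 1 to 23 (short UV-A) and 1655 to 2323 (blue). In uvr8-2 they ran from 0 to 34 (UV-B), 0 to 2 (short UV-A), 0 to 76 (long UV-A) and 1649 to 2230 (blue), and in cry1cry2 from 1138 to 1561 (UV-B), 283 to 444 (short UV-A), 0 to 3 (long UV-A) and 3 to 53 (blue). Differences from Ler ran in uvr8-2 from 1 to 18 (UV-B), 0 to 1 (short UV-A) and 0 to 1 (long UV-A), and in cry1cry2 from 0 to 1 (UV-B), 0 to 3 (short UV-A), 0 to 1 (long UV-A) and 1 to 91 (blue). Genotype counts ran from 662 to 3911 and 0 to 9 (uvr8-2, UVA+B and blue0), and from 35 to 223 and 64 to 115 (cry1cry2, UVA+B and blue0).

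Among 4992 values of named genes without 1 library, 497 lost a call and 18 gained one; with DESeq2 1 of 941 lost and 58 gained, and with the block 0 of 994 lost and 64 gained. Of 480 list tests, 123 lost the camera call with an estimated correlation, 84 lost and 10 gained it with fry, and 2 lost and 27 gained it with the block. Depth limits low genes most: a gene at 0 counts in a group is bounded by 3 counts over the group.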

Other observations

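The comparisons of total UV (UVA+B minus UV0) and of the genotypes under UVA, UVA350 and UV0 were chosen after the data were seen, and were not repeated without single libraries. Camera called further lists for these comparisons, which are not described here. In Ler, total UV raised 22 of 24 flavonoid and phenylpropanoid enzyme genes, which make UV-absorbing pigments (22 adjusted over the list alone, median log2 change 2.53, camera adjusted p = 1.9e-22, adjusted p = 0.0565 with an estimated correlation), and 4 of 5 sinapate ester genes (4 over the list alone, camera adjusted p = 0.000102, adjusted p = 0.0211 with an estimated correlation). MYB12, the flavonol regulator, rose by 5.31 ± 0.45 in Ler and by 2.56 ± 0.45 in uvr8-2. Heat shock genes, which encode chaperones and their regulators, rose in 2 of 10 cases in Ler (5 over the list alone, median 1.37, camera adjusted p = 0.00125, adjusted p = 0.104 with an estimated correlation). They rose in 5 of 10 cases in cry1cry2 (median 1.54, camera adjusted p = 0.00769, adjusted p = 0.175 with an estimated correlation). In uvr8-2 their median was 0.41 (0 of 10 called, camera adjusted p = 0.0409, adjusted p = 0.305 with an estimated correlation). In uvr8-2, 2 of the 24 flavonoid genes rose (14 over the list alone, median 0.70, camera adjusted p = 1.29e-09, adjusted p = 0.249 with an estimated correlation). In cry1cry2, 22 rose and 1 fell (22 and 1 over the list alone, median 3.23, camera adjusted p = 7.77e-19, adjusted p = 0.076 with an estimated correlation), and 8 of 20 salicylate defence genes fell (8 over the list alone, camera adjusted p = 0.0148, adjusted p = 0.503 with an estimated correlation). The salicylate median was -0.60 in cry1cry2, -0.63 in Ler (2 of 20 lower, camera adjusted p = 0.0022, adjusted p = 0.391 with an estimated correlation) and -0.47 in uvr8-2 (0 of 20, camera adjusted p = 0.00029, adjusted p = 0.348 with an estimated correlation). Between cry1cry2 and Ler its median difference was -0.06 (camera adjusted p = 0.822).

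In all, edgeR called 3551 genes for total UV in Ler (1892 higher, 1659 lower), 154 in uvr8-2 (136 and 18) and 6809 in cry1cry2 (3247 and 3562). The difference between uvr8-2 and Ler was called for 133 genes, 22 higher and 111 lower in uvr8-2. Flavonoid enzyme genes had a lower response in 9 of 24 cases (21 over the list alone, median difference -1.63, camera adjusted p = 3.49e-25, adjusted p = 0.0488 with an estimated correlation), and auxin response genes had a median difference of 0.92 (0 of 14 called, 3 higher over the list alone, camera adjusted p = 1.38e-05, adjusted p = 0.257 with an estimated correlation). The photolyase gene UVR3 stood at 21.6 ± 8.4 CPM in Ler under UVA+B and 1.35 ± 0.52 CPM under UV0, and at 2.75 ± 0.84 and 1.27 ± 0.45 CPM in uvr8-2 (SD, n = 2). The difference between cry1cry2 and Ler was called for 13 genes. Without the libraries of over 1% chloroplast counts, the counts were 3369, 161 and 5195 within genotypes and 122 and 7 for the differences of uvr8-2 and cry1cry2.

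Against Ler, uvr8-2 gave 49 calls under UVA, 2 under UVA350 and 27 under UV0, and cry1cry2 gave 675, 1918 and 1454. Without the libraries of over 1% chloroplast counts, the counts were 22, 3 and 18 for uvr8-2 and 349, 1774 and 1359 for cry1cry2.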
